A study of Mus musculus with 12 samples.

How the data were processed

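RNA was sequenced from bone marrow-derived macrophages (BMDMs) of mice in 12 libraries, 3 in each of 4 groups. The groups were floxed Scap control cells (WT) and cells deleted for Scap in the myeloid lineage through Lyz2-Cre (KO), each untreated or after 6 h with Candida albicans. Per the labels, RNA was taken with TRIzol, libraries were made with the Optimal Dual-mode mRNA kit and sequencing was done at BGI. The untreated libraries carry the numbers 1 to 3 and the infected ones 4 to 6. The labels do not say whether libraries of a group come from separate mice, separate cultures or 1 pool.

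Per the submitters' processing notes, reads were aligned with Bowtie2 to GRCm38.p6 and genes were quantified with RSEM 1.3.1. The deposited table gives for each library an expected count per gene, estimated by RSEM without normalization, for 15974 genes. Of the deposited expected count values, 94.1% had no decimals as printed, and the total per library ran from 16240827 to 17176736. The deposited TPM (transcripts scaled by gene length and library) and FPKM (fragments scaled likewise) of the same libraries were made by the authors from the same quantification. The authors' log2 fold change and p-value columns (an adjusted p, called q-value in the file headers) come from DESeq2 per the file headers, with version and settings not stated. Each listed gene was of the type mRNA, and none had a count of 0 in every library. A second deposited file repeated 48 of the same value columns, identical value for value, and was not used again.

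The analysis started from the deposited expected counts, rounded to whole numbers. Genes passed filterByExpr of edgeR 4.0.16 by group, which left 11792. Libraries were scaled by TMM, and a quasi-likelihood model with 1 mean per group was fitted over all 12 libraries (glmQLFit with robust=TRUE, then glmQLFTest, two-sided). P-values were adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. The contrasts tested were the Candida effect in WT cells and in KO cells, the genotype effect (KO minus WT) in untreated and in infected cells, the genotype effect averaged over both conditions, and the interaction (Candida effect in KO minus that in WT). Levels are given as library-scaled counts (edgeR CPM with TMM factors), mean ± SD over 3 libraries. Effects are log2 fold changes ± SE, the SE taken from the fold change and its F statistic. R 4.3.3, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9 were used.

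Lists of genes were written before the data were examined, as were the contrasts, the tests, the rule for named genes and most of the alternative settings. The lists cover sterol synthesis and uptake (SREBP2 targets), fatty acid synthesis and desaturation (SREBP1 targets), the SCAP-SREBP machinery, LXR targets and sterol efflux, glycolysis, the hypoxia response outside glycolysis, the TCA cycle, the nuclear genes of the respiratory chain, the pentose phosphate pathway, fungal recognition and CARD9 signalling, inflammatory cytokines and mediators, chemokines, NF-kB feedback, immediate early genes, interferon-stimulated genes, the inflammasome, the phagocyte oxidase, alternative activation and resolution, antigen presentation, the lysosome, the unfolded protein and integrated stress response, proliferation and macrophage identity. Marker lists cover neutrophils, dendritic cells, lymphoid cells, mast cells and basophils, erythroid cells and platelets, and stromal and endothelial cells. Check lists cover genotype check genes, mitochondrially encoded transcripts and sex-linked genes. Each list was tested on voom values with limma's camera at its preset correlation of 0.01, adjusted over the lists of a contrast. Camera with an estimated correlation stands beside it, and fry was an alternative. A list needed at least 3 tested members. Members called are counted over all genes and adjusted over the list alone.

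In each contrast the text names genes by a rule: 13 genes fixed in advance, the 8 largest changes in each direction among called genes, and from each list the 4 called members of smallest p. The largest changes were taken among genes with a mean log2 CPM of at least 3, a symbol that is not a clone or predicted-gene name and, except for the interaction, no overlap between the libraries of the groups compared. Of the SREBP2 targets 3 are counted in the list results but neither named nor drawn, whatever their rank. A few more genes are named from the lists they belong to, with values from the same fit. Mmp8 was singled out after its values were seen.

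The alternative settings fixed then were DESeq2 size factors in the same fit, no filter on low counts, a filter at a mean of 50 counts, the DESeq2 Wald test, limma-voom, limma-trend on log2 of TPM with a pseudocount of 1 or 0.1, a fit of only the 2 groups compared, an adjusted p under 0.01, a change of at least 2-fold, replicate numbers as a block in the genotype contrasts, and leaving out each library in turn. Lists were run with DESeq2 size factors, no filter, the replicate block, each library left out, camera with an estimated correlation and fry, and not under the other settings. A pair of alternatives was added after the data were seen: scaling by library totals without a composition factor, since TMM factors ran from 1.13 to 1.18 in untreated and from 0.852 to 0.877 in infected libraries, and genotype contrasts without Lyz2. Lists were run with the first of these only. A change of sign between a pair of uncalled results was counted as unchanged. KEGG and Reactome sets given in the deposited annotation columns were tested with camera after the data were seen.

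Counts for 11792 genes were simulated for the genotype contrast in infected cells and tested in the same way. edgeR recovered 61 of 67 genes changed 1.5-fold, 67 of 67 changed 2-fold and 66 of 66 changed 4-fold, and called 12 unchanged genes (5.83% of its calls). DESeq2 recovered 58, 65 and 66 and called 4 unchanged genes. Camera in both forms and fry called a planted list of 20 genes, and 0, 0 and 1 of 30 unchanged lists. Lists of correlated genes were not simulated.

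These totals leave genes with a few counts per library, such as Il6 in untreated cells, without a usable fold change. Counting error is not the whole spread: the common biological coefficient of variation was 3.66%. Gene IDs and coordinates are those of the deposited table and the reference for GRCm38.p6. Coordinates are left out for genes that the table places on more than 1 scaffold (Hk2 and Tnf among those named). Reads were not used here, so exon use in Scap was not measured.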

Results

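RNA was sequenced from mouse bone marrow-derived macrophages (BMDMs) of floxed Scap controls (WT) and of mice whose myeloid cells carry Lyz2-Cre and lose Scap (KO). Cells were left untreated or exposed for 6 h to Candida albicans, a pathogenic yeast. Each of the 4 groups has 3 libraries, and the total count per library ran from 16240827 to 17176736. Scap is the escort protein that carries the sterol-sensing transcription factors SREBP1 and SREBP2 to the Golgi for activation. Levels below are library-scaled counts (CPM with TMM factors), mean ± SD with n = 3. Effects are log2 fold changes ± SE with 3 libraries per group, and adjusted p-values come from edgeR. Gene lists were tested with camera and fry from limma. Camera FDR is the adjusted p with a fixed correlation between genes, and estimated FDR the one with an estimated correlation. Gene positions are on GRCm38.p6.

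Scap itself (gene ID 235623, chromosome 9, 110333288 to 110384949) was measured in every library. Its level was 22.8 ± 0.613 in untreated WT and 19.4 ± 1.11 in untreated KO cells (SD, n = 3), a log2 fold change of -0.24 ± 0.069 (adjusted p = 0.0215). In infected cells it was 21.2 ± 0.773 in WT and 15.1 ± 1.53 in KO, a log2 fold change of -0.48 ± 0.08 (adjusted p = 4.49e-05). Counts per gene do not show which exons were read, so the deleted part of Scap was not visible. The call in untreated cells ended with the DESeq2 Wald test (adjusted p = 0.0954), with limma-trend on TPM (0.053 and 0.0695), and without WT untreated library 2 (0.087) or 3 (0.0918) or KO untreated library 2 (0.112) or 3 (0.0592). The interaction of Scap was -0.24 ± 0.11 (adjusted p = 0.21).

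Lyz2 (gene ID 17105, chromosome 10, 117277541 to 117282272) encodes the macrophage lysozyme, and its locus carries Cre in the KO mice. It fell from 6092 ± 95.8 to 25.3 ± 1.32 CPM in untreated cells and from 4799 ± 25.4 to 42.0 ± 3.6 in infected cells (SD, n = 3). Lyz2 took 0.412 to 0.723% of the counts of WT libraries and 0.00281 to 0.00399% of those of KO libraries. Lyz1 (gene ID 17110, chromosome 10, 117287795 to 117292868), its neighbour and paralog, fell by log2 1.31 ± 0.083 in untreated and 1.44 ± 0.087 in infected cells. Of the 4 genotype check genes tested, 3 fell in untreated and 4 in infected KO cells, with the same counts adjusted over the list alone (camera FDR = 2.93e-11, estimated FDR = 0.00128; infected, camera FDR = 4.38e-12, estimated FDR = 0.000907). The last of them, Nnt, is a gene whose loss marks a common substrain. Only its infected effect was called, -0.25 ± 0.077 (adjusted p = 0.0253). The infected call of Nnt ended with the DESeq2 Wald test (0.056) and without infected WT library 4 (0.114) or 6 (0.0983) or infected KO library 4 (0.15) or 5 (0.113).

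**Figure D1:**
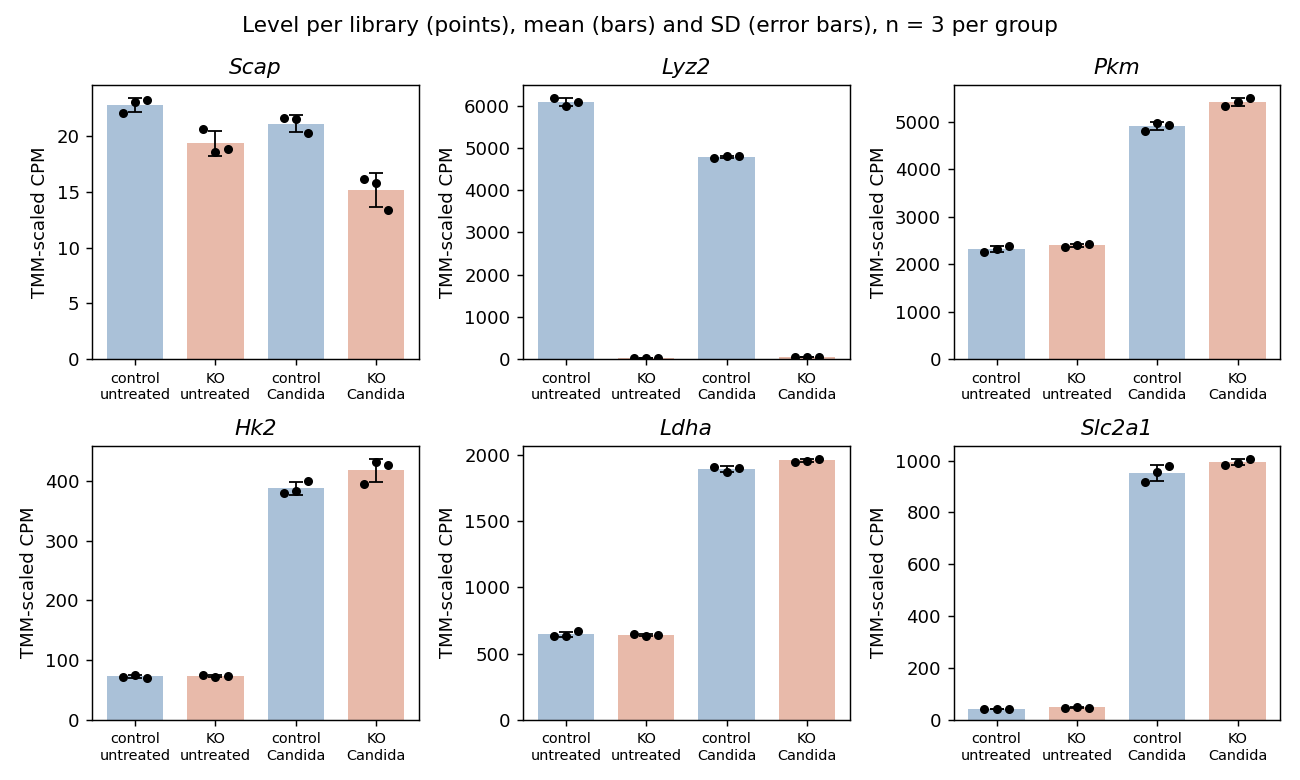
Levels of Scap, Lyz2, Pkm, Hk2, Ldha and Slc2a1 in the 12 libraries (CPM with TMM factors), with bars for the mean of 3 libraries per group and whiskers for the SD. Lyz2 is close to absent in both KO groups, and the 4 glycolytic genes are higher in infected cells of both genotypes, also when scaled by library totals.

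The first principal component of log2 CPM held 88.3% of the variance and separated infected libraries (63.2 to 67.2) from untreated ones (−67.6 to −62.8). The second held 3.6% and separated WT (11 to 16.5) from KO libraries (−15.5 to −9.5). Of 11792 genes tested, Candida changed 9494 in WT cells (4574 higher, 4920 lower) and 9367 in KO cells (4564 higher, 4803 lower). Genotype changed 1137 genes in untreated cells (639 higher, 498 lower in KO) and 1725 in infected cells (777 higher, 948 lower). The balance of higher and lower genes depended on scaling. With library totals it was 2499 and 7762 for Candida in WT, 2530 and 7585 in KO, 393 and 734 for genotype untreated and 577 and 1084 infected, so that in untreated cells the majority turned. By genotype most changes of at least 2-fold were lower in KO cells (19 higher and 100 lower untreated, 13 and 156 infected). The most abundant gene was Ctsb, a lysosomal protease, in untreated libraries (1.45 to 1.59% of counts) and Hmox1, the inducible heme oxygenase, in infected ones (1.65 to 1.99%).

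What a 6 h encounter with Candida does to control macrophages is the question of the Candida effect in WT cells. Camera called the chemokine and glycolysis lists higher and the proliferation list lower, calls that were lost with an estimated correlation (0.124, 0.0766 and 0.27). The glucose transporter Slc2a1 (gene ID 20525, chromosome 4, 119108745 to 119138802) rose from 41.9 ± 1.15 to 951 ± 30.7 CPM (SD, n = 3), 22.7-fold. The neutrophil chemokine Cxcl2 rose by log2 7.56 ± 0.07, and the fungal receptor Clec4e (Mincle) by 5.09 ± 0.049. The replication helicase gene Mcm2 fell, with a log2 fold change of -2.77 ± 0.063.

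Glycolysis had 19 of 22 members higher, 2 lower and 1 not called (camera FDR = 9.26e-09, estimated FDR = 0.0766). The same counts came out adjusted over the list alone. Pkm (gene ID 18746, chromosome 9, 59656368 to 59679375), which encodes the pyruvate kinases PKM1 and PKM2, rose from 2323 ± 65 to 4901 ± 81 CPM, log2 1.08 ± 0.033. Hexokinase Hk2 (gene ID 15277) rose by 2.42 ± 0.043, lactate dehydrogenase Ldha (gene ID 16828, chromosome 7, 46842274 to 46855627) by 1.56 ± 0.035, the lactate exporter Slc16a3 by 3.50 ± 0.045 and Pfkfb3, which makes an activator of phosphofructokinase, by 3.57 ± 0.054. Hif1a, the hypoxia-inducible factor, rose by 1.59 ± 0.043. Of the hypoxia response outside glycolysis, 13 of 14 members rose and 1 fell, among them Egln3 (5.36 ± 0.10), Bnip3 (3.17 ± 0.055) and Vegfa (2.91 ± 0.054), with camera FDR = 1.53e-06, estimated FDR = 0.133. Scaled by library totals the median of all genes lay lower by log2 0.44 (shift −0.436), and Pkm came to 0.64, still higher, with 19 glycolysis members higher and 3 lower. Limma-trend on TPM gave Pkm 0.61.

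The inflammatory program was called almost in full. All 12 inflammatory cytokines and mediators rose (camera FDR = 1.64e-05, estimated FDR = 0.124). So did all 15 chemokines (camera FDR = 1.41e-07, estimated FDR = 0.124) and all 16 genes of NF-kB feedback (camera FDR = 7.66e-10, estimated FDR = 0.136). Tnf (gene ID 21926) went from 17.8 ± 2.36 to 567 ± 19.7 CPM. Il6 had 0 to 2 counts per untreated WT library and 61 to 70 after Candida. The median of the cytokine list was log2 5.65, and 4.99 without Csf3, which had no count in a group. Of immediate early genes 16 of 18 rose (camera FDR = 1.59e-07, estimated FDR = 0.124), with Atf3 at 2.35 ± 0.038 and Ier3 at 3.90 ± 0.058. All 25 interferon-stimulated genes rose, among them Irf1 (2.46 ± 0.046) and Stat2 (1.91 ± 0.058), with camera FDR = 5.64e-13, estimated FDR = 0.27. Each of these counts was the same adjusted over the list alone. The largest rises of all included Cxcl3 (9.63 ± 0.09), Ptgs2, the inducible cyclooxygenase (9.62 ± 0.12), and Acod1, which makes itaconate (6.80 ± 0.075).

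Genes that recognise fungi and signal through CARD9 had 15 of 21 members higher and 6 lower (camera FDR = 0.00108, estimated FDR = 0.272), with Clec4n (Dectin-2) at 4.13 ± 0.059 and Malt1 at 3.99 ± 0.049. The beta-glucan receptor Clec7a (Dectin-1) rose by log2 0.69 ± 0.043, and by less with library totals (0.25). Antigen presentation had 12 of 15 higher and 3 lower, with Cd86 at 2.37 ± 0.073 (camera FDR = 0.00281, estimated FDR = 0.345). Proliferation had 23 of 24 members lower and none higher, with Mcm2 at -2.77 ± 0.063 and Mcm6 at -2.45 ± 0.05 (camera FDR = 3.14e-08, estimated FDR = 0.27). Of the inflammasome list 6 rose (Nlrp3, 2.61 ± 0.044) and 4 fell (Nlrp1b, -3.39 ± 0.076), of the phagocyte oxidase 5 rose (Ncf4, 0.80 ± 0.041) and 1 fell, and of alternative activation and resolution 8 rose (Il10, 3.17 ± 0.099) and 4 fell. The camera p of these was 0.346, 0.0568 and 0.0566. Fry called them (1.47e-08, 2.17e-08 and 9.63e-11), as did camera the oxidase with no filter (0.0422) and alternative activation with library totals (0.00434) and without untreated WT library 1 (0.0496) or infected WT library 5 (0.0464). Macrophage identity had 5 higher (Cd14, 2.55 ± 0.042) and 6 lower (Cebpa, -1.17 ± 0.044). Its median (-0.069) and camera (0.848) pointed down, while its mean (0.14) and fry (0.00335) pointed up. Adjusted over the lists alone, all these counts stayed the same. Among the largest falls were Hpgd, which degrades prostaglandins (-5.72 ± 0.094), Sesn1, a p53 target (-4.62 ± 0.061), and Nfatc2 (-4.47 ± 0.11).

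Of SREBP2 targets 11 rose, among them Sqle (0.85 ± 0.06). Another 7 fell, with Dhcr7 at -1.67 ± 0.088 (camera FDR = 0.379, estimated FDR = 0.392). SREBP1 targets had 4 higher (Acss2, 2.99 ± 0.085) and 12 lower (Fads1, -1.04 ± 0.05), the SCAP-SREBP machinery 4 and 2, LXR targets 3 and 5, the TCA cycle 9 and 8, and the pentose phosphate pathway 5 (Pgd, 1.18 ± 0.034) and 2. Their camera p was 0.304, 0.78, 0.427, 0.664 and 0.111, while fry called these and the SREBP2 targets (the largest, 0.0138). The nuclear genes of the respiratory chain had 28 of 40 higher and 3 lower (camera FDR = 0.0323, estimated FDR = 0.385). The lysosome had 15 of 22 higher and 3 lower, with Ctsz at 1.17 ± 0.04 (camera FDR = 0.0177, estimated FDR = 0.385). The unfolded protein and integrated stress response had 10 of 15 higher and 2 lower, with Atf4 at 1.41 ± 0.038 (camera FDR = 0.02, estimated FDR = 0.136). Adjusted over the lists alone the counts did not change. With library totals the medians of SREBP2 targets, the SCAP-SREBP machinery, the TCA cycle, the respiratory chain (0 higher, 28 lower), the pentose phosphate pathway, the lysosome (3 higher, 15 lower) and the stress response (6 higher, 7 lower) turned negative. SREBP2 targets then had 5 higher and 13 lower and the TCA cycle 3 and 16. The camera calls of the respiratory chain (0.308), the lysosome (0.788) and the stress response (0.0887) were then lost. Without infected WT library 6 the respiratory chain had an adjusted p of 0.0714.

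Markers of other cells were followed as well. Of 11 neutrophil markers 8 rose and 1 fell (Camp, 1.24 ± 0.052, camera FDR = 0.0175, estimated FDR = 0.272). All 3 erythroid and platelet markers rose, with Pf4 at 1.22 ± 0.04 (camera FDR = 0.0462, estimated FDR = 0.305). This call was lost with DESeq2 size factors (0.0508), with no filter (0.291) and without untreated WT library 2 (0.109) or 3 (0.103) or infected WT library 4 (0.0734), 5 (0.104) or 6 (0.107). Lymphoid markers had 2 of 3 higher (Il7r, 1.91 ± 0.04) and 1 lower, and stromal and endothelial markers 1 of 3 higher (Kdr, 1.24 ± 0.075), with camera p of 0.567 and 0.379 against 9.49e-10 and 4.28e-07 by fry. Both dendritic cell markers tested (Itgax and Ccr7) and both mast cell and basophil markers tested (Gata2 and Kit) rose. With 2 members these lists had no list test, and Kit lost its call with limma-trend on TPM (0.0771 and 0.124). Of genotype check genes 2 of 4 fell, Nnt and Lyz2 (-0.34 ± 0.037; camera FDR = 0.197, fry 1.08e-05). The 13 mitochondrially encoded transcripts and 5 sex-linked check genes had 0 members tested. Counts adjusted over each list alone were the same. A change of at least 2-fold was met by 3232 of the 9494 genes. With library totals 24.4% of called genes were higher, against 48.2% with TMM.

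Whether KO macrophages answer Candida is the question of the Candida effect in KO cells. Slc2a1 rose from 47.8 ± 1.62 to 994 ± 12.2 CPM (SD, n = 3), log2 4.38 ± 0.043, and Pkm from 2400 ± 31.7 to 5415 ± 82.2, log2 1.17 ± 0.033. Clec4e rose by 5.07 ± 0.049, Cxcl2 by 7.15 ± 0.067 and Slc7a11, the cystine importer, by 6.55 ± 0.057, while Hpgd fell, with a log2 fold change of -6.22 ± 0.10. Of the genes called in WT cells, 4224 rose and 4441 fell in KO cells too, where independent lists would share 1770.3 and 2004, and 22 were called in opposite directions (14 and 8). Across genes the effects in the 2 genotypes correlated with Pearson r = 0.96, though genes are not independent replicates.

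Glycolysis again had 19 of 22 members higher and 2 lower (camera FDR = 3.61e-09, estimated FDR = 0.0657), with Hk2 at 2.52 ± 0.043, Ldha at 1.61 ± 0.035 and Hif1a at 1.70 ± 0.043. Scaled by library totals the median of all genes shifted by −0.415 and Pkm came to 0.76 (0.72 with limma-trend on TPM), still higher. The hypoxia response had 13 of 14 higher (camera FDR = 1.38e-06, estimated FDR = 0.107; median 1.94, and 1.83 without Adm). Cytokines had 12 of 12 higher (camera FDR = 4.09e-05, estimated FDR = 0.107), with a median of 5.56, and 5.05 without Lif. Chemokines had 15 of 15 (camera FDR = 9.29e-07, estimated FDR = 0.107), NF-kB feedback 16 of 16 (camera FDR = 1.07e-09, estimated FDR = 0.13) and immediate early genes 16 of 18 higher (camera FDR = 6.69e-07, estimated FDR = 0.107). With library totals 13 chemokines and 16 immediate early genes were higher. Il6 went from 0 to 3 counts per library to 33 to 40. Interferon-stimulated genes had 25 of 25 higher, with Irf1 at 2.08 ± 0.046 (camera FDR = 1.16e-11, estimated FDR = 0.334), and proliferation 20 of 24 lower and 1 higher, with Mcm2 at -2.83 ± 0.066 (camera FDR = 2.06e-06, estimated FDR = 0.334). Fungal recognition had 15 of 21 higher (camera FDR = 0.00264, estimated FDR = 0.334), where Clec7a rose by 0.44 ± 0.042 with TMM, by 0.025 with library totals (adjusted p = 0.569) and not with TPM (−0.009). Adjusted over each list alone these counts were the same.

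Alternative activation had 8 of 13 higher (camera FDR = 0.0471, estimated FDR = 0.159, lost with DESeq2 size factors, 0.0529), and antigen presentation 11 of 15 (camera FDR = 0.0166, estimated FDR = 0.485). The stress response had 13 of 15 higher (camera FDR = 0.00276, estimated FDR = 0.107) and the lysosome 16 of 22 (camera FDR = 0.0211, estimated FDR = 0.461). The respiratory chain had 27 of 40 higher (camera FDR = 0.0347, estimated FDR = 0.461), and 0.0761 without infected KO library 4. With library totals the lysosome had 4 higher and 14 lower and the respiratory chain 0 and 27, with the direction of both lists turned (adjusted p = 0.981 and 0.368). The medians of the SCAP-SREBP machinery, LXR targets, the TCA cycle, the pentose phosphate pathway and the stress response also turned negative. SREBP2 targets had 7 higher (Sqle, 1.20 ± 0.081) and 10 lower (Dhcr7, -2.20 ± 0.10), with a camera p of 0.884 pointing down and a fry adjusted p of 2.7e-06 pointing up (5 higher and 18 lower with library totals). The inflammasome had 6 higher and 4 lower, the oxidase 5 and 1, macrophage identity 5 and 6, SREBP1 targets 4 and 9, the SCAP-SREBP machinery 4 and 3, LXR targets 2 and 4, the TCA cycle 9 and 8, and the pentose phosphate pathway 5 and 1. Camera called none of these (adjusted p from 0.107 to 0.782). Macrophage identity had a mean of 0.002 against a median of -0.12, and LXR targets a mean of -0.18 against a median of 0.017. Neutrophil markers had 7 of 11 higher and 1 lower (Camp, 1.48 ± 0.066, camera FDR = 0.0254, estimated FDR = 0.334), erythroid and platelet markers 3 of 3 higher (camera 0.0561, library totals 0.0123), lymphoid markers 2 of 3, stromal markers 1 of 3, and both dendritic and both mast cell markers tested were higher. Adjusted over each list alone these counts were the same, except that 3 of 4 genotype check genes fell rather than 2.

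**Figure D2:**
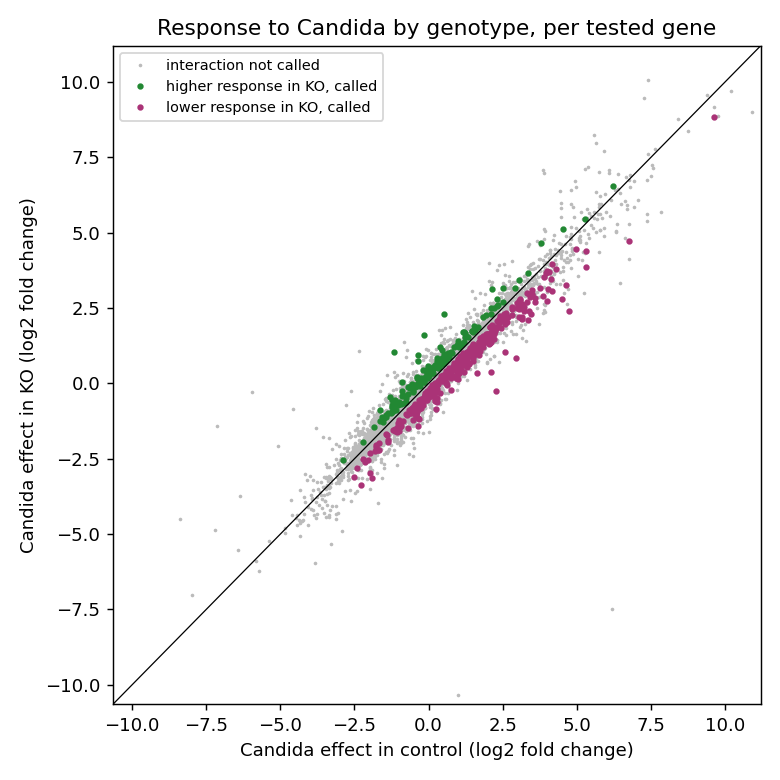
Candida effect in WT cells (horizontal, log2) against that in KO cells (vertical, log2) for each gene tested, with the 559 genes called for an interaction coloured. Points lie along the diagonal (Pearson r = 0.96 across genes), and scaling by library totals moves both axes down by about 0.4 (−0.436 and −0.415).

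What differs in resting KO macrophages, which carry Lyz2-Cre and lose Scap, is the question of the genotype effect in untreated cells. Of SREBP2 targets 20 of 24 fell, of SREBP1 targets 10 of 17, and of neutrophil markers 8 of 11, with 1 higher. The desaturase Scd2 fell from 63.0 ± 2.62 to 16.4 ± 0.459 CPM (SD, n = 3). Epas1, which encodes HIF-2α, rose from 10.3 ± 0.886 to 37.0 ± 1.86. Pkm was 2323 ± 65 in WT and 2400 ± 31.7 in KO cells, a log2 fold change of 0.047 ± 0.033 that did not pass the test (adjusted p = 0.439).

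SREBP2 targets had 20 of 24 members lower and none higher (camera FDR = 2.49e-42, estimated FDR = 8.58e-06), and 22 lower adjusted over the list alone. The squalene epoxidase Sqle fell by log2 1.42 ± 0.075 and Cyp51 by 1.25 ± 0.066. SREBP1 targets had 10 of 17 lower, 12 adjusted over the list alone (camera FDR = 1.4e-15, estimated FDR = 0.000281), with the desaturase Scd1 at -2.50 ± 0.20, Fads2 at -2.26 ± 0.16 and the fatty acid synthase Fasn at -0.65 ± 0.045. The SCAP-SREBP machinery had 4 of 7 lower by both counts (camera FDR = 0.000103, estimated FDR = 0.0166): Scap, Srebf1 (-0.21 ± 0.044), Srebf2 (-0.62 ± 0.041) and Insig1, the retention partner of Scap (-0.96 ± 0.053). LXR targets had 2 higher (Apoe and Pltp, 0.34 ± 0.068) and 1 lower (Lpcat3, -0.21 ± 0.048), or 4 and 2 adjusted over the list alone. Camera did not call them (0.0599), but did with no filter (0.0436), with the replicate block (0.0284) and without untreated WT library 2 (0.0402) or KO library 3 (0.00443).

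Glycolysis did not move as a list (camera FDR = 0.793): 2 of 22 members rose and 3 fell, or 3 and 3 adjusted over the list alone. Pdk1, which inhibits pyruvate dehydrogenase, rose by 0.99 ± 0.06, while the aldolase Aldoc (-0.93 ± 0.085) and the transporter Slc2a3 (-0.51 ± 0.074) fell. Slc2a1 rose by 0.19 ± 0.047, a call lost without untreated WT library 2 (adjusted p = 0.0615) or KO library 2 (0.0607). Hk2 was at 0.01 ± 0.046 (adjusted p = 0.943), Ldha at -0.004 ± 0.034 (0.968) and Hif1a at -0.026 ± 0.045 (0.822). The hypoxia response had 1 higher and 1 lower, the TCA cycle 1 lower (0 adjusted over the list alone), the respiratory chain 0 called of 40 (edgeR; 0 adjusted over the list alone) and the pentose phosphate pathway 1 higher (1 higher and 2 lower adjusted over the list alone), with camera p of 0.876, 0.443, 0.859 and 0.862. The respiratory chain member of smallest p, Atp5o (-0.14), had an adjusted p of 0.0548, which came to 0.013 with library totals.

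Several lists of immune genes were called higher by camera in untreated KO cells, with small changes. Each of these list calls was lost with an estimated correlation (from 0.061 to 0.714). Fungal recognition had 9 of 21 higher by both counts (camera FDR = 2.68e-08, estimated FDR = 0.0761), with Clec7a at 0.44 ± 0.043 and Lgals3 at 0.33 ± 0.036. Immediate early genes had 6 of 18 higher, 7 adjusted over the list alone (Egr2, 1.11 ± 0.096, camera FDR = 1.57e-06, estimated FDR = 0.077). NF-kB feedback had 6 of 16 higher, 9 adjusted over the list alone (Tnfaip3, 0.35 ± 0.053, camera FDR = 9.71e-05, estimated FDR = 0.247). Chemokines had 4 of 15 higher by both counts (Cxcl16, 0.32 ± 0.043, camera FDR = 0.00162, estimated FDR = 0.219; fry 0.0643). Antigen presentation had 3 of 15 higher, 7 adjusted over the list alone, with H2-DMa at 0.41 ± 0.072 (camera FDR = 1.97e-05, estimated FDR = 0.219, fry 0.0567). Macrophage identity had 6 of 12 higher, 8 adjusted over the list alone, with Csf1r at 0.16 ± 0.035 (camera FDR = 1.39e-05, estimated FDR = 0.148). The lysosome had 12 of 22 higher, 15 adjusted over the list alone, with the protease Ctss at 0.41 ± 0.034 (camera FDR = 5.81e-12, estimated FDR = 0.061). The phagocyte oxidase had 3 of 7 higher, 4 adjusted over the list alone (camera FDR = 0.0279, estimated FDR = 0.227), a call lost with library totals (0.089) and without untreated WT library 3 (0.0533) or KO library 1 (0.108). Interferon-stimulated genes had 0 of 25 called, also adjusted over the list alone, with a median of 0.14 (camera FDR = 0.0249, estimated FDR = 0.714; fry 0.581, without WT library 3 0.231, without KO library 1 0.587).

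Tnf was the only cytokine of 12 called higher (log2 0.28 ± 0.087, adjusted p = 0.0445; 1 adjusted over the list alone; camera 0.434). Its call was lost with library totals (0.0629), with a filter at 50 counts (0.0531), with limma-trend on TPM (0.0903 and 0.102), in a fit of the 2 groups alone (0.106) and without untreated WT library 2 (0.154) or 3 (0.199) or KO library 1 (0.19) or 2 (0.164). Proliferation had 11 of 24 lower, 19 adjusted over the list alone, with Rrm2 at -0.51 ± 0.059 (camera FDR = 5.81e-12, estimated FDR = 0.136). The stress response had 3 of 15 lower, with 3 lower and 1 higher adjusted over the list alone (Hspa5, -0.14 ± 0.034, camera FDR = 0.00462, estimated FDR = 0.0682), and 5 lower with library totals. The inflammasome had 2 of 10 higher and alternative activation 5 higher (Cd36, 0.22 ± 0.036) and 1 lower (Chil3, -0.97 ± 0.053), the same adjusted over the lists alone, with camera p of 0.0891 and 0.0639. The first was called without WT library 2 (0.0316), the second with library totals (0.0358, though with 3 higher), with the replicate block (0.0455) and without WT library 1 (0.0492) or KO library 3 (0.0288).

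Neutrophil markers moved with genotype: 8 of 11 were lower and 1, Mmp8, was higher (0.29 ± 0.038), and 9 were lower adjusted over the list alone (camera FDR = 2.74e-22, estimated FDR = 0.00133). Camp, a granule peptide, fell from 52.5 ± 2.09 to 18.2 ± 2.18 CPM, and the granule enzymes Elane and Mpo fell by log2 1.17 ± 0.077 and 1.25 ± 0.073. Other markers had few members called: Itgax (Cd11c) rose by 1.48 ± 0.12 and was 1 of 2 dendritic markers tested, Il7r by 0.38 ± 0.041 (1 of 3 lymphoid), Pf4 by 0.22 ± 0.04 (1 of 3 erythroid and platelet), and none of 3 stromal and 1 of 2 mast cell markers changed. That 1, Kit (-0.82 ± 0.23, adjusted p = 0.0204), lost its call with the DESeq2 Wald test (0.054), limma-trend on TPM (0.0738 and 0.0549) and without WT library 1 (0.0664) or 3 (0.0525) or KO library 1 (0.0831) or 2 (0.069). The counts were the same adjusted over each list alone. Camera adjusted p was 0.434 for lymphoid (fry 0.00246), 0.757 for erythroid and 0.876 for stromal markers, and the lymphoid and erythroid medians (-0.079 and -0.22) lay below 0 while camera pointed up. The sialic acid lyase Npl (gene ID 74091, chromosome 1, 153503016 to 153549714) fell from 39.9 ± 2.42 to 5.41 ± 1.26 CPM. Of the 1137 genes 119 changed at least 2-fold. Without untreated WT library 2 there were 688, and without library 3 there were 715.

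How infected KO macrophages differ from WT ones is the question of the genotype effect in infected cells. Sterol synthesis genes were lower in KO cells, a list call that held with an estimated correlation. Interferon-stimulated genes were lower too, but that list call did not hold (estimated FDR = 0.0726). Cyp51, an enzyme of the late sterol pathway, was 39.9 ± 0.754 CPM in WT and 11.3 ± 0.295 in KO cells (SD, n = 3), and Usp18, induced by interferon, was 143 ± 14.9 and 92.8 ± 9.82. Gclc, which makes the first step of glutathione synthesis, was higher in KO cells (331 ± 21.7 and 608 ± 28.3). Pkm was 4901 ± 81 in WT and 5415 ± 82.2 in KO cells, higher by log2 0.14 ± 0.033 (adjusted p = 0.00196).

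SREBP2 targets had 21 of 24 members lower by both counts (camera FDR = 1.29e-36, estimated FDR = 1.52e-05), with Idi1 at -1.99 ± 0.15 and Cyp51 at -1.83 ± 0.069. SREBP1 targets had 9 of 17 lower, 11 adjusted over the list alone (camera FDR = 1.76e-10, estimated FDR = 0.000907), with Scd2 at -2.00 ± 0.066 and Scd1 at -2.67 ± 0.27. In the SCAP-SREBP machinery Scap, Srebf2 (-0.71 ± 0.042) and Insig1 (-0.75 ± 0.052) fell and 1 gene, Mbtps1, rose (2 adjusted over the list alone). Its mean (-0.23) and camera pointed down and its median (0.005) up (camera FDR = 0.0205, estimated FDR = 0.0907). LXR targets had 3 higher (Apoe, 0.43 ± 0.064) and 2 lower (Abcg1, -0.36 ± 0.078), or 5 and 2 adjusted over the list alone (camera 0.115; 0.0457 without KO library 4).

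Glycolysis had 3 of 22 higher and 2 lower, or 5 and 2 adjusted over the list alone, with a median of 0.046 (camera FDR = 0.0965). The list was called with no filter (0.0459), by fry (0.016) and without infected KO library 4 (0.0445). Pdk1 (0.71 ± 0.056), the neuronal enolase Eno2 (0.51 ± 0.10) and Pkm rose, and Aldoc (-0.85 ± 0.093) fell. Hk2 was at 0.11 ± 0.039 (adjusted p = 0.0593; 0.0308 without WT library 6, 0.0141 without KO library 4), Ldha at 0.047 ± 0.034 (0.409), Slc2a1 at 0.063 ± 0.035 (0.265) and Hif1a at 0.081 ± 0.04 (0.202). The interaction of Pkm was 0.096 ± 0.046 (adjusted p = 0.273) and that of Slc2a1 -0.13 ± 0.059 (0.255), so the genotype effects on them were not shown to differ between conditions. The hypoxia response had 3 higher and 2 lower, the TCA cycle 0 and 1, the respiratory chain 1 and 1, and the pentose phosphate pathway 1 and 1 (2 and 1 adjusted over the list alone, the others the same). Their camera p was 0.366, 0.192, 0.856 and 0.91. The TCA gene, Acod1 (-0.29 ± 0.055), had an adjusted p of 0.0502 with the replicate block.

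Interferon-stimulated genes had 22 of 25 members lower and none higher, and 25 lower adjusted over the list alone. The camera FDR was 2.4e-34, and the estimated FDR 0.0726 with a correlation of 0.82 in this list. Irf1 was at -0.36 ± 0.042, Stat2 at -0.44 ± 0.055 and Usp18 at -0.62 ± 0.077. Outside the list, Iigp1 was at -1.79 ± 0.25, and Ifit1bl1 (-1.59 ± 0.26) lost its call in a fit of the 2 groups alone (0.0588). Cytokines had 1 of 12 higher and 7 lower by both counts (camera FDR = 3.58e-05, estimated FDR = 0.0726), with Il18 at -0.57 ± 0.075, Il12b at -0.98 ± 0.19 and Nos2 at -1.11 ± 0.15. Tnf was 567 ± 19.7 CPM in WT and 479 ± 10.6 in KO cells (log2 -0.24 ± 0.053, adjusted p = 0.00307; 0.0514 and 0.0615 with limma-trend on TPM). Il6 had 61 to 70 counts per WT library and 33 to 40 per KO library (adjusted p = 0.00183; 0.295 with limma-trend on TPM and the pseudocount 0.1). Chemokines had 3 higher and 7 lower of 15, or 3 and 9 adjusted over the list alone (camera FDR = 0.0104, estimated FDR = 0.367), with Ccl5 at -0.96 ± 0.12, Ccl4 at -0.38 ± 0.051 and Cxcl2 at 0.17 ± 0.043.

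Lysosomal genes had 13 of 22 higher, or 14 higher and 1 lower adjusted over the list alone (camera FDR = 4.33e-09, estimated FDR = 0.0907), with Atp6v0d2 at 1.03 ± 0.079 and Ctsl at 0.40 ± 0.036. Fungal recognition had 7 of 21 higher, 8 adjusted over the list alone (camera FDR = 0.00499, estimated FDR = 0.367), with Lgals3 at 0.29 ± 0.036 and Clec7a at 0.19 ± 0.043. The other lists were not called by camera. Alternative activation had 5 higher (Arg1, 0.64 ± 0.089) and 1 lower (Chil3, -1.10 ± 0.048), antigen presentation 4 lower (Cd40, -0.56 ± 0.071), macrophage identity 4 higher (Cebpa, 0.37 ± 0.045) and 3 lower, the oxidase 2 higher and 1 lower (Ncf1, -0.30 ± 0.038), and immediate early genes 3 higher. NF-kB feedback and the inflammasome had 1 lower each, the stress response 2 higher (Sesn2, 0.32 ± 0.083), and proliferation 1 higher and 3 lower. Adjusted over the list alone, alternative activation had 6 higher, macrophage identity 5 and the oxidase 3, the rest being the same. Camera adjusted p was 0.0965, 0.0965, 0.245, 0.799, 0.356, 0.661, 0.661, 0.976 and 0.661 in this order, with alternative activation called without KO library 4 (0.0296) and antigen presentation without WT library 6 (0.0253). Macrophage identity, proliferation and the stress response had a mean and median of different sign.

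Neutrophil markers were again lower: 9 of 11, with Mmp8 higher, by both counts (camera FDR = 4.25e-19, estimated FDR = 0.0023). Camp was 124 ± 0.649 CPM in WT and 50.9 ± 3.05 in KO cells, and Elane fell by log2 1.15 ± 0.074. Among other markers Itgax (0.71 ± 0.11, 1 of 2 dendritic), Il7r (0.30 ± 0.037, 1 of 3 lymphoid) and Pf4 (0.21 ± 0.039, 1 of 3 erythroid and platelet, with 1 lower) rose, and Kit (-1.09 ± 0.21, 1 of 2 mast cell) and Kdr (-0.54 ± 0.073, 1 of 3 stromal) fell, the same adjusted over the lists alone. Camera adjusted p was 0.356 for lymphoid (fry 0.00145), 0.496 for erythroid and 0.0706 for stromal markers (fry 0.000281, without WT library 5 0.0407). Of the 1725 genes 169 changed at least 2-fold. In both conditions 229 genes were higher and 215 lower in KO cells, where independent lists would share 42.1 and 40, and 33 were called in opposite directions (25 and 8). The genotype effects correlated across genes with r = 0.339, and genes are not independent replicates.

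**Figure D3:**
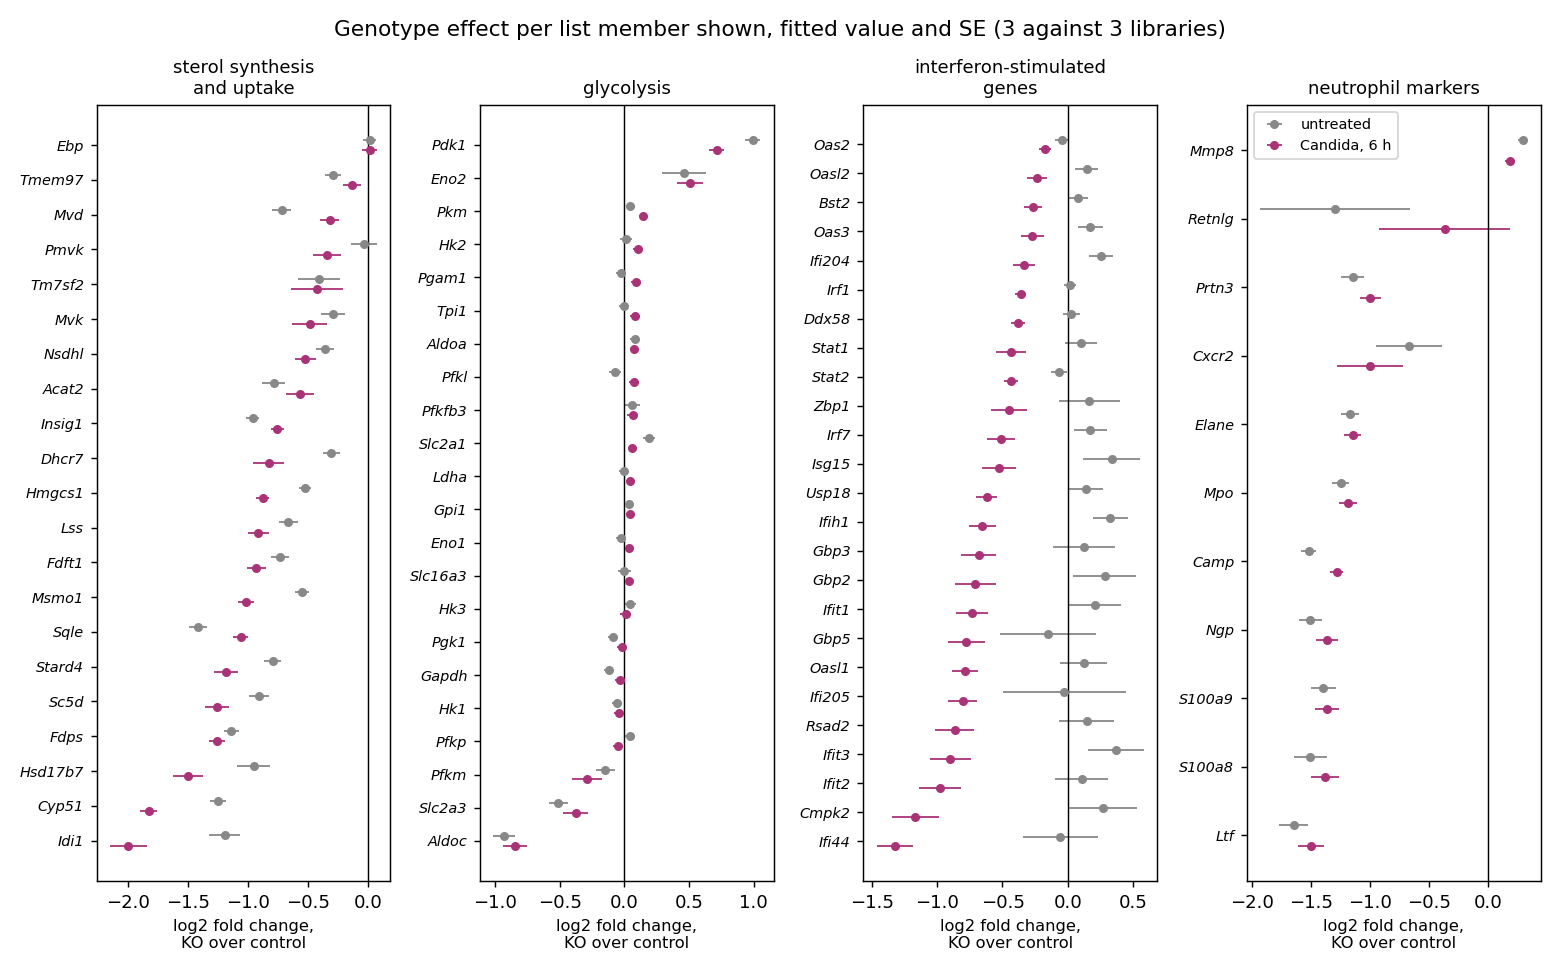
Genotype effect (KO minus WT, log2 fold change with SE) for members of 4 lists, sterol synthesis, glycolysis, interferon-stimulated genes and neutrophil markers, in untreated (grey) and infected (magenta) cells; 3 sterol genes of the list are not drawn. Most sterol and neutrophil genes lie below 0 in both conditions and interferon-stimulated genes in infected cells, while glycolysis members lie on both sides, with a list median averaged over conditions of 0.025 that turns to −0.003 with library totals.

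Averaged over both conditions, the genotype effect asks what loss of Scap does whether or not Candida is there. SREBP2 and SREBP1 targets fell and the lysosome list rose. The larger KEGG lysosome set (122 genes, median 0.049) was not called by camera with an estimated correlation (adjusted p = 0.663). In KO cells 992 genes were higher and 894 lower, a balance that turned with library totals (621 higher, 1244 lower) and with limma-trend on TPM (575 and 1039, or 568 and 964). Of the 126 that changed at least 2-fold, 14 were higher and 112 lower. SREBP2 targets had 22 of 24 lower, 23 adjusted over the list alone, with Fdps at -1.20 ± 0.045 (camera FDR = 8.79e-46, estimated FDR = 6.3e-06). SREBP1 targets had 13 of 17 lower by both counts, with Fasn at -0.60 ± 0.034 (camera FDR = 6.33e-16, estimated FDR = 0.000258). Neutrophil markers had 9 of 11 lower and 1 higher by both counts (camera FDR = 2.43e-22, estimated FDR = 0.00131). The SCAP-SREBP machinery had 4 of 7 lower and 1 higher, 4 and 2 adjusted over the list alone (camera FDR = 0.00109, estimated FDR = 0.0348), and the lysosome 15 of 22 higher, or 16 (camera FDR = 1.83e-13, estimated FDR = 0.044). These, with the genotype check genes (camera FDR = 6.81e-13, estimated FDR = 0.000686), are all the averaged list calls that held with an estimated correlation. Across the 6 contrasts such calls were limited to SREBP2 targets, SREBP1 targets, neutrophil markers and genotype check genes in each of the 3 genotype contrasts, the SCAP-SREBP machinery in untreated cells and on average, and the lysosome on average. No list call of a Candida contrast or of the interaction held in that way.

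Other averaged calls were lost with an estimated correlation. Fungal recognition had 13 of 21 higher, 15 adjusted over the list alone (camera FDR = 5.66e-07, estimated FDR = 0.11; with library totals 7 higher and 1 lower), and immediate early genes 6 of 18 (camera FDR = 0.000271, estimated FDR = 0.212). Macrophage identity had 6 of 12 higher and 2 lower, 9 and 2 adjusted over the list alone (camera FDR = 0.00137, estimated FDR = 0.329), and alternative activation 6 of 13 and 1, or 8 and 1 (camera FDR = 0.0195, estimated FDR = 0.0939). Interferon-stimulated genes had 6 of 25 lower, or 8 (camera FDR = 1.3e-09, estimated FDR = 0.339, fry 0.0846), and proliferation 7 of 24, or 8 (camera FDR = 0.00206, estimated FDR = 0.534, fry 0.145). NF-kB feedback had 5 of 16 higher, or 6 (camera FDR = 0.02, estimated FDR = 0.534; 2 higher with library totals). Its call was lost by fry (0.123) and without infected WT library 6 (0.0501) or untreated KO library 1 (0.0927) or 2 (0.0787). Pkm was higher by log2 0.096 ± 0.023 (adjusted p = 0.00334) and Slc2a1 by 0.13 ± 0.029 (0.00226), in a glycolysis list with 5 members higher and 4 lower by both counts (camera FDR = 0.453).

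The interaction asks whether the response to Candida itself differs in KO cells. The Candida effect was lower in KO cells for 9 of 25 interferon-stimulated genes, 4 of 15 chemokines and 3 of 12 cytokines. Camera called these lists, but not with an estimated correlation (0.206, 0.206 and 0.269), and fry did not call cytokines (0.0706). Tnf rose by log2 4.99 ± 0.07 in WT and 4.47 ± 0.069 in KO cells, an interaction of -0.53 ± 0.10 (adjusted p = 0.00393). Gclc rose more in KO cells, by 3.14 ± 0.057 against 2.15 ± 0.056, and Ccnd1, the cyclin D1 gene, fell from 148 to 30.2 ± 3.47 CPM in WT and from 150 to 14.3 ± 1.65 in KO cells (SD, n = 3). Of 559 genes called, 147 had a higher and 412 a lower Candida effect in KO cells, 24 of them by at least 2-fold. Without untreated WT library 2 or 3 there were 347 and 338, and without infected WT library 4 or KO library 4 there were 371 and 372.

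Interferon-stimulated genes had a median interaction of -0.76, with 9 of 25 called lower and 21 adjusted over the list alone (camera FDR = 1.94e-29, estimated FDR = 0.206). Irf1 was at -0.38 ± 0.064 and Ddx58 (the RNA sensor RIG-I) at -0.41 ± 0.086, and outside the list Ifi213 was at -1.15 ± 0.21. Chemokines had 4 of 15 lower, 9 adjusted over the list alone (camera FDR = 1.85e-08, estimated FDR = 0.206). Cytokines had 3 of 12 by both counts, with Il18 at -0.61 ± 0.11 (camera FDR = 0.00824, estimated FDR = 0.269). NF-kB feedback had 4 of 16, 6 adjusted over the list alone, with Nfkbiz at -0.46 ± 0.077 (camera FDR = 0.000114, estimated FDR = 0.337). Immediate early genes had 2 of 18, 7 adjusted over the list alone (camera FDR = 2.06e-05, estimated FDR = 0.216), and antigen presentation 2 of 15, 6 adjusted over the list alone (camera FDR = 1.32e-07, estimated FDR = 0.25). Fry gave 0.0706 for cytokines, 0.0858 for NF-kB feedback and 0.0662 for antigen presentation, and cytokines had 0.0639 without untreated KO library 1. With library totals 2 chemokines and 1 immediate early gene were called lower. Across 1562 genes at least 2-fold higher with Candida, the median effect was 1.81 in WT and 1.73 in KO cells. Of these genes 57.8% had an interaction below 0, with 173 called lower and 41 called higher.

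Glycolysis had a median interaction of 0.05 with 1 of 22 called by both counts (camera FDR = 0.219). That 1, Pdk1 (-0.28 ± 0.083, adjusted p = 0.0444), was not called with library totals (0.0704), the DESeq2 Wald test (0.0665), limma-trend on TPM (0.221 and 0.219), the replicate block (0.0506) or without any 1 of 9 libraries (from 0.0552 without untreated KO library 3 to 0.147 without infected WT library 4). Hk2 was at 0.099 ± 0.06 (adjusted p = 0.423), Ldha at 0.051 ± 0.048 (0.658) and Hif1a at 0.11 ± 0.061 (0.381). SREBP2 targets had 5 of 24 lower and 2 higher, or 8 and 4 adjusted over the list alone (camera FDR = 0.0239, estimated FDR = 0.206), with Cyp51 at -0.58 ± 0.099, Msmo1 at -0.47 ± 0.089 and Hmgcs1 at -0.35 ± 0.074. Proliferation had 3 of 24 higher, 11 adjusted over the list alone, with Cenpa at 0.32 ± 0.076 (camera FDR = 1.06e-06, estimated FDR = 0.337, fry 0.109). The stress response had 1 of 15 higher by both counts, Sesn2 (0.57 ± 0.11), with camera FDR = 0.0239, estimated FDR = 0.216. It was lost without infected WT library 4 (0.0571) or infected KO library 5 (0.0524).

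Fungal recognition had 2 of 21 lower, 6 adjusted over the list alone (camera FDR = 0.0239, estimated FDR = 0.495), and the inflammasome 2 of 10, 3 adjusted over the list alone (camera FDR = 0.0322, estimated FDR = 0.337). The oxidase had 2 of 7 lower, 3 adjusted over the list alone, with Ncf1 at -0.27 ± 0.052 (camera FDR = 0.026, estimated FDR = 0.328). Macrophage identity had 3 of 12 lower (4 adjusted over the list alone) and 1 higher, Cebpa (0.43 ± 0.061), with camera FDR = 0.0239, estimated FDR = 0.495. With library totals the inflammasome and the oxidase had 1 lower each. Fry gave 0.149 for fungal recognition, 0.0706 for the inflammasome and 0.261 for macrophage identity. Without untreated WT library 3 the inflammasome had 0.117, the oxidase 0.0561 and macrophage identity 0.0738. Without infected WT library 4 fungal recognition had 0.0661 and the inflammasome 0.179. Without untreated KO library 1 fungal recognition had 0.0826, the oxidase 0.0719 and macrophage identity 0.145, and without library 2 the inflammasome had 0.0527. Without infected KO library 4 fungal recognition had 0.0817 and macrophage identity 0.0563. The remaining lists were not called by camera, from SREBP1 targets (1 higher, 0.843) and the hypoxia response (1 higher, 0.458) to the lysosome (0 called, 0.911) and neutrophil markers (0 called by edgeR and adjusted over the list alone, 0.204; 0.00277 without untreated KO library 3).

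The authors' own DESeq2 table, at a q-value under 0.05, called 8711 and 8595 genes for the Candida effect in WT and KO cells, and 653 and 957 for the genotype effect in untreated and infected cells. Of these, 8499, 8419, 627 and 945 were called here in the same direction and 0 in the opposite one.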

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

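All 8 tests of explanations below and comparisons per library were chosen after the result was seen, while regroupings were planned before. Results here are given because the Candida effect differed between WT and KO cells by the interaction test (559 genes). Patterns weighed further down are genotype effects. Camera called 13 lists, none with an estimated correlation (0.206 to 0.495), and fry did not call 7. The medians of the 13 lists, as log2 Candida effect in KO minus that in WT, were -0.178 for SREBP2 targets, -0.065 for fungal recognition, -0.608 for inflammatory cytokines, -0.681 for chemokines, -0.141 for NF-kB feedback, -0.277 for immediate early genes, -0.762 for interferon-stimulated genes, -0.087 for inflammasome, -0.041 for oxidase, -0.331 for antigen presentation, 0.082 for stress response, 0.198 for proliferation, -0.083 for macrophage identity. Genes with a lower Candida effect in KO cells were Ccl12 -2.339, Cmpk2 -1.431, Il27 -1.366, Calhm6 -1.288, Ifit3 -1.263, Ifi213 -1.151, Ccnd1 -1.095, Egr2 -1.003, Il16 -1, Ifih1 -0.978, Cxcl3 -0.792, Itgax -0.769, Usp18 -0.762, Fcgr1 -0.679, Il18 -0.613, Cyp51 -0.576, Cd40 -0.564, Kdr -0.546, Tnf -0.526, Dhcr7 -0.52. Further ones were Mertk -0.492, Abcg1 -0.486, Msmo1 -0.465, Nfkbiz -0.464, Ddx58 -0.409, Irf1 -0.375, Tnfaip3 -0.374, Stat2 -0.371, Hmgcs1 -0.35, Ier2 -0.35, Tap2 -0.336, Casp4 -0.316, Pdk1 -0.278, Ncf1 -0.272, Nfkbie -0.264, Cd14 -0.257, Clec7a -0.248, Malt1 -0.244, Cxcl16 -0.231, Nfkb1 -0.224, Rac2 -0.205, Casp1 -0.197, Ccl9 -0.178. Genes with a higher one were Lyz2 1.073, Gclc 0.997, Kif14 0.759, Lrp8 0.681, Poc1a 0.651, Emilin2 0.621, Slc20a2 0.61, Gdf15 0.583, Sesn2 0.572, Cebpa 0.429, Bub1 0.391, Cenpa 0.317, Ccna2 0.301, Aacs 0.281, Vegfa 0.265, Srebf1 0.23. Some, Pdk1 among them, lose their call under an alternative. Lower effects include genes higher in infected KO cells (Itgax, Pdk1) and a stronger fall (Ccnd1). Lyz2 had only 456 to 658 counts per KO library.

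Regrouping libraries shows what a division regardless of group gives. For the Candida effects in WT and KO cells (9494 and 9367 genes) the highest of the other divisions called 0 and 0. For the genotype effects in untreated and infected cells (1137 and 1725) it called 1 and 0. In each, 1 of 10 divisions, the real one, called as many, and 10 are too few splits for a share under 0.05. For the averaged genotype effect (1886 genes) 1 of 100 divisions called as many, the real one, and the highest other called 559, so chance can be excluded at 0.05. For the interaction (559 genes) 3 of 100 called as many, a share under 0.05. These divisions exchange genotype labels within conditions, which assumes no genotype effect at all. Divisions that mix genotypes carry the averaged genotype effect as spread, so they cannot decide whether the interaction arose by chance. The highest other, 1886, exchanges the genotype labels in infected cells and so measures the averaged genotype effect. The other, 603, regroups untreated libraries only, moving WT 2 and 3 and KO 1 and 2.

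The first pattern weighed is the lower level of neutrophil markers in KO cells (9 of 11 averaged over conditions, with Mmp8 higher). Scaling between libraries is argued against, since with library totals the list mean was still lower in KO cells, with a log2 difference (KO minus WT) of -1.201 (SE 0.128 between libraries) untreated and -1.026 (SE 0.081) infected. A smaller admixture of 1 kind of neutrophil-lineage cell could not be told apart. Averaged effects differed beyond their error (chi-square per df 204, not computed without Mmp8 at 0.24). The others lay from -0.83 (Retnlg) to -1.58 (Ltf). The criterion was widened after Mmp8 was seen higher. Whether fewer such cells or lower expression in macrophages accounts for it stays open.

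The second is the lower level of interferon-stimulated genes in infected KO cells, a list call by camera with the fixed correlation that was lost with an estimated one (0.0726; 0.206 for the interaction). Taken per library, the list mean was lower in infected KO cells, with a log2 difference of -0.611 (SE 0.13 between libraries). That 1 library decides it is argued against, since without each of the 6 infected libraries the difference was -0.52 (SE 0.12, without WT library 4) or further from 0. Scaling between libraries is argued against too (-0.629, SE 0.121, with library totals). A weaker response of all induced genes is argued against too: none of 10000 matched sets of other induced genes had so low a median interaction (permutation p = 1e-04, the smallest that 10000 sets can give). The list median was -0.762, against a median of -0.148 and a 95% range of -0.374 to 0.084 for the sets. The sets take genes as independent, while the members move together (correlation 0.82). Compared per library, which does not, the mean difference between the list and its matched genes had an interaction of log2 -0.551 (SE 0.125, 12 libraries). Of 400 exchanges of genotype labels within conditions, 8 gave a difference as large (exact permutation p = 0.02). Such exchanges assume no genotype effect on that difference in either condition. Interferon itself was not measured as protein, so a biological cause was not tested and stays open.

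The third is the far lower level of Lyz2, Lyz1 and Npl in KO cells. A strain segment around Scap or Lyz2 stays open, as it need not raise the share of genes called. Within 5 Mb this was 17 of 116 (Scap) and 2 of 33 (Lyz2), against 16% elsewhere (one-sided Fisher exact p = 0.886). Npl lies on chromosome 1. Lyz2 reads counted for Lyz1 remain a possible account of Lyz1: its fall was 2.65% of the fall of Lyz2 in untreated and 3.4% in infected cells, a ratio of 1.28 that this explanation allows, but it does not cover Npl. Cre sits at the Lyz2 locus itself. Which of the Cre allele and the loss of Scap lowers Lyz1 or Npl stays open, as 0 libraries carry 1 of them alone.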

How the results depend on the processing

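Most results kept their direction and their side of the threshold. Over all alternatives, counts of called genes stayed within 1.5 times the reported count in 282 comparisons and moved further in 78. Named genes were unchanged in 10589, lost their call in 689, gained one in 32 and reversed in 46. Lists were unchanged in 2116, lost a call in 113, gained one in 61 and reversed in 6. The lower SREBP2 targets, SREBP1 targets and neutrophil markers in KO cells kept their calls in all 3 genotype contrasts under each alternative run for lists. These were DESeq2 size factors, library totals, no filter, the replicate block, each library left out, the estimated correlation and fry. Pkm stayed higher with Candida in both genotypes (log2 0.61 to 1.11 in WT, 0.72 to 1.20 in KO) and in infected KO against infected WT cells (0.13 to 0.16), without an interaction call in any alternative (0.075 to 0.12). What limits the results: 3 libraries per group, no Cre-positive group without floxed Scap, and replicates of unstated origin. Libraries of 16240827 to 17176736 counts leave genes with few counts, such as Il6 in untreated cells, without a usable fold change.

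A change of at least 2-fold leaves fewer genes by construction: 3232 (1594 higher, 1638 lower) for the Candida effect in WT cells, 3159 (1545 higher, 1614 lower) for that in KO cells. The genotype effect kept 119 (19 higher, 100 lower) untreated, 169 (13 higher, 156 lower) infected, 126 (14 higher, 112 lower) averaged, and the interaction 24 (5 higher, 19 lower). An adjusted p under 0.01, stricter as well, left 626 (353 higher, 273 lower) for the untreated genotype effect, 1019 (406 higher, 613 lower) infected, 1111 (583 higher, 528 lower) averaged and 217 (32 higher, 185 lower) for the interaction. The DESeq2 Wald test gave 302 lower genes for the untreated genotype effect and 88 higher ones for the interaction (the cause was not tested).

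Scaling by library totals and leaving Lyz2 out were chosen after the data were seen. With library totals or with limma-trend on TPM (pseudocount 1, then 0.1), Candida effects have no composition factor and move down by construction (−0.436 in WT and −0.415 in KO with library totals). Higher genes in WT came to 2499, 2343 and 2340, and lower ones to 7762, 7872 and 7845. Those in KO came to 2530, 2385 and 2396, and lower ones to 7585, 7709 and 7722. For the genotype effect higher and lower genes came to 393 and 734, 324 and 463, 318 and 389 untreated (707 in total in the last), 487 and 888, 482 and 909 infected with TPM, and 621 and 1244, 575 and 1039, 568 and 964 averaged. The majority so turned from higher to lower untreated and averaged. The interaction had 96 higher genes with TPM and a pseudocount of 1, and 351 (86 higher, 265 lower) with 0.1. The cause of these last changes was not tested. Genes of small Candida effect reversed in these 3 settings, in WT Srebf1 (-0.306, -0.327, -0.335), Srebf2 (-0.176, -0.205, -0.209), Atp5b (-0.096, -0.131, -0.131), Ndufa4 (-0.046, -0.098, -0.098), Cox5a (-0.006, -0.047, -0.048), Cyc1 (-0.094, -0.167, -0.169), Tkt (-0.039, -0.073, -0.073), and in KO Srebf1 (-0.056, -0.088, -0.09), Srebf2 (-0.242, -0.269, -0.277), Arl4c (-0.085, -0.118, -0.119), Atp5b (-0.035, -0.07, -0.07), Cox6a1 (-0.078, -0.117, -0.117), Ndufa4 (-0.088, -0.126, -0.126), Tkt (-0.077, -0.113, -0.113), and with TPM alone Clec7a (-0.009, -0.009), Cyc1 (-0.039, -0.04). With library totals the respiratory chain (0.308 in WT, 0.368 in KO) and the lysosome (0.788 and 0.981) reversed and were not called under Candida. The stress response in WT (0.0887) and the oxidase in untreated cells by genotype (0.089) lost a call. Gained were alternative activation with Candida in WT (0.00434) and by genotype in untreated cells (0.0358), erythroid markers with Candida in KO (0.0123) and the TCA cycle in the averaged genotype effect (0.0481). Leaving out Lyz2 changed no count by more than 1.5 times and ended the interaction call of Aacs alone.

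Camera with an estimated correlation ended these calls, given as adjusted p (the cause was not tested). For the Candida effect in WT cells: glycolysis 0.0766, hypoxia 0.133, respiratory chain and lysosome 0.385, fungal recognition and neutrophil 0.272, cytokines, chemokines and immediate early 0.124, NF-kB feedback and stress response 0.136, interferon and proliferation 0.27, antigen presentation 0.345, erythroid 0.305. For the Candida effect in KO cells: glycolysis 0.0657, hypoxia, cytokines, chemokines, immediate early and stress response 0.107, respiratory chain and lysosome 0.461, fungal recognition, interferon, proliferation and neutrophil 0.334, NF-kB feedback 0.13, alternative activation 0.159, antigen presentation 0.485. For the genotype effect in untreated cells: fungal recognition 0.0761, chemokines and antigen presentation 0.219, NF-kB feedback 0.247, immediate early 0.077, interferon 0.714, oxidase 0.227, lysosome 0.061, stress response 0.0682, proliferation 0.136, macrophage identity 0.148. For the genotype effect in infected cells: SCAP-SREBP machinery and lysosome 0.0907, fungal recognition and chemokines 0.367, cytokines and interferon 0.0726. For the averaged genotype effect: fungal recognition 0.11, NF-kB feedback and proliferation 0.534, immediate early 0.212, interferon 0.339, alternative activation 0.0939, macrophage identity 0.329. For the interaction: SREBP2 targets, chemokines and interferon 0.206, fungal recognition and macrophage identity 0.495, cytokines 0.269, NF-kB feedback, inflammasome and proliferation 0.337, immediate early and stress response 0.216, oxidase 0.328, antigen presentation 0.25.

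Fry asks whether the members of a list move, on balance, in 1 direction, and does not compare them with other genes, so it answers another question by construction. With Candida it called more lists. In WT these were SREBP2 targets and inflammasome 1.47e-08, SREBP1 targets 0.000328, SCAP-SREBP machinery 0.0138, LXR targets 0.00335, TCA cycle 2.81e-07, pentose phosphate 2.82e-09, oxidase 2.17e-08, alternative activation 9.63e-11, lymphoid 9.49e-10, stromal 4.28e-07, genotype check 1.08e-05, and macrophage identity, reversed to up (0.00335). In KO they were SREBP1 targets 0.00665, SCAP-SREBP machinery 0.000522, LXR targets 0.00413, TCA cycle 5.8e-07, pentose phosphate 4.31e-09, inflammasome 5.24e-08, oxidase 1.19e-07, lymphoid 1.1e-09, erythroid 8.36e-08, stromal 9.76e-05, genotype check 0.0065, and SREBP2 targets, reversed to up (2.7e-06). By genotype fry called lymphoid 0.00246 untreated, glycolysis 0.016, lymphoid 0.00145, stromal 0.000281 infected, and LXR targets 0.0469, stress response 0.0182, lymphoid 0.000144, stromal 0.00173 averaged. It did not call chemokines 0.0643, interferon 0.581, antigen presentation 0.0567 untreated, nor NF-kB feedback 0.123, interferon 0.0846, proliferation 0.145 averaged. For the interaction it called stromal 0.0228, genotype check 0.0336, and not fungal recognition 0.149, cytokines and inflammasome 0.0706, NF-kB feedback 0.0858, antigen presentation 0.0662, proliferation 0.109, macrophage identity 0.261.

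Without a filter, with more genes tested, the oxidase was called with Candida in WT (0.0422) and erythroid markers were not (0.291). By genotype LXR targets were called untreated (0.0436) and averaged (0.0338), and glycolysis infected (0.0459). DESeq2 size factors ended the calls of erythroid markers in WT (0.0508) and alternative activation in KO (0.0529) with Candida. The replicate block gave 1272, 1707, 1949 and 621 genes for the untreated, infected and averaged genotype effects and the interaction, and called LXR targets untreated (0.0284) and averaged (0.0291) and alternative activation untreated (0.0455). The cause of these list changes was not tested. Residuals of WT and KO libraries correlated at −0.087 to 0.07 (same number, −0.087 to 0.058), so the numbers were not taken as pairs. A fit of only the 2 groups compared does not apply to the averaged effect and the interaction, which use all 4 groups.

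Leaving out 1 library, which leaves fewer samples, gave 688 to 1393 (373 to 764 higher, 315 to 629 lower) genes for the untreated genotype effect, lowest without WT library 2, and 338 to 729 (69 to 221 higher, 269 to 545 lower) for the interaction, lowest without untreated WT library 3. Lists whose call changed have these lowest and highest adjusted p, with the libraries named in the report. With Candida in WT: respiratory chain 0.024 to 0.0714, alternative activation 0.0464 to 0.0597, erythroid 0.0443 to 0.109. In KO: respiratory chain 0.024 to 0.0761. By genotype, untreated: LXR targets 0.00443 to 0.215, interferon 0.00114 to 0.587, inflammasome 0.0316 to 0.281, oxidase 0.00831 to 0.108, alternative activation 0.0288 to 0.149. Infected: LXR targets 0.0457 to 0.208, glycolysis 0.0445 to 0.202, alternative activation 0.0296 to 0.196, antigen presentation 0.0253 to 0.239, stromal 0.0407 to 0.103. Averaged: LXR targets 0.00861 to 0.102, NF-kB feedback 0.000147 to 0.0927, LXR targets being called without untreated WT library 2, untreated KO library 3 or library 4 of either infected group. For the interaction: fungal recognition 0.00192 to 0.0826, cytokines 0.00352 to 0.0639, inflammasome 0.0154 to 0.179, oxidase 0.00765 to 0.0719, stress response 0.00946 to 0.0571, macrophage identity 0.00153 to 0.145, neutrophil 0.00277 to 0.687. Leaving out a library ended 439 calls of named genes and gained 10.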

Other observations

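The KEGG and Reactome sets given in the deposited annotation were tested with camera after the data were seen, 330 and 930 sets per contrast. With Candida the IL-17 signalling set (63 genes) was higher in WT and KO cells, with a median log2 fold change of 1.19 and 1.12 (adjusted p = 0.0152 and 0.0148 with an estimated correlation). The 12 Reactome sets of smallest p in WT cells were higher too, with medians of 0.767 to 0.891. The first of them were activation of NF-kB in B cells (61 genes, 0.00367 and 0.00452), regulation of ornithine decarboxylase (49 genes, 0.00529 and 0.00601) and ROS sensing by NFE2L2 (51 genes, 0.0119 and 0.0117). The KEGG proteasome (45 genes) had a like median of 0.86 in WT and 0.863 in KO cells, with 0.0416 and 0.0693. How many genes these sets share was not counted. DNA replication (35 genes) was lower, a call that ended with an estimated correlation (0.181 and 0.211).

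By genotype, cholesterol biosynthesis (25 genes) was lower in KO cells, with adjusted p = 0.00127 untreated, 0.00179 infected and 0.000788 averaged, each with an estimated correlation. Steroid biosynthesis (17 genes) gave 0.00801, 0.0114 and 0.00608, and antimicrobial peptides (18 genes, also lower) 0.0638, 0.0285 and 0.0433. Some calls ended with an estimated correlation. Among them were the KEGG lysosome set (122 genes, higher), with 0.326 untreated, 0.699 infected and 0.663 averaged. Averaged, fatty acid metabolism (51 genes, lower) had 0.0914 and fatty acyl-CoA biosynthesis (25 genes, lower) 0.184.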
